A study of Mus musculus with 9 samples.

How the data were processed

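Chromatin accessibility had been measured by ATAC-seq, sequenced on an Illumina NextSeq, in age-associated B cells sorted by flow cytometry from the spleen of 20-week-old MRL/lpr bone-marrow chimeras. There were 9 samples, 3 each of Tlr9 KO, P915H and WT. The authors' notes name Trim Galore 0.6.5, Bowtie2 2.3.3, SAMtools, Picard 2.18.12, MACS2 and limma with build mm10, without saying what each was used for. The deposited table gives log2 values for 61540 peaks in the 9 samples, and a companion table gives their coordinates. How the authors normalized the values, and whether they called peaks on pooled or single samples, is not given in the sources used here. The antilogs sum to 0.987 to 1.014 times the nominal total of CPM in each sample, which makes the deposited unit log2 of a value scaled as CPM of reads in peaks. Read counts per sample are therefore unknown, and no counting interval is given.

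At every peak, the mean over the 3 genotypes was the same for replicate numbers 1, 2 and 3 to within rounding. A replicate effect per peak had thus been removed before deposit. This takes degrees of freedom out of the values, so the SD within a genotype understates the spread. The test fixed before the data were examined was limma with genotype alone. That test counts 6 residual degrees of freedom per peak, although the values hold 4, and the reported test therefore adds a term for the replicate number. This change departs from the plan. It was made on the construction of the values, before the calls of both versions were compared, and the counts of both are given. Simulated data tested both versions, with 200 changed peaks and 5 draws. With the term, 4.84% of unchanged peaks had an unadjusted p under 0.05 and 10.5% of calls were false. Without it these were 11.43% and 30.8%. With the term, 6.8% of changes of 0.5 on the log2 scale were recovered, 58.8% of changes of 1, 97.6% of changes of 2 and 100% of changes of 3. Equal replicate numbers cannot be tested as pairs in these values, because removing the effect forces deviations of samples with the same number apart (median r -0.546, against 0.306 for other pairs across genotypes).

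All 9 samples entered 1 fit in limma 3.58.1 (R 4.3.3) with an intensity trend, tested two-sided with Benjamini-Hochberg adjustment over all peaks of a comparison and a threshold of 0.05. Fold changes are on the log2 scale, and SE is that of the fit. No peak was filtered out and no pseudocount was added. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

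Peaks were assigned to the gene body they overlap, or to the nearest within 100 kb, from a gene table of the same assembly that has no strand. Of the 61540 peaks, 40305 (65.5%) lay within a gene, 18800 (30.6%) outside one but within 100 kb and 2435 (3.96%) farther away, and 14708 genes had a peak. Assignment by distance does not show which gene a peak regulates. Start sites, motif sets and a GC correction need strand or sequence and were not analysed here.

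The 19 gene lists were fixed before the data were examined, each as all peaks of its genes, with 6 of them markers of other cell types (T, natural killer, macrophage and monocyte, neutrophil, dendritic and erythroid cells). Each was tested against the other peaks with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry, which asks whether the peaks of a list move on balance in one direction, were alternatives. Effects of KO and P915H against WT were compared by their covariance beside 20 simulated draws with shared WT samples. Called peaks within 10 Mb of Tlr9, Ptprc and the heavy chain constant genes were compared with the rest by Fisher's exact test, since chimeras are often sorted by alleles of the latter loci.

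The peaks named were chosen by a rule fixed in advance. It takes up to 10 higher and 10 lower peaks per comparison with the largest fold change among those past the threshold with no overlap between the groups, 1 per gene. It adds up to 12 such peaks of the fixed lists, the 2 peaks of each list with the smallest p, and every peak in or within 2 kb of Tlr9. Some peaks that the rule names are not reported here. The heavy chain peaks other than the one near Ighe, the peak clusters and the genes with many calls were chosen after their values were seen. Alternatives covered the replicate term, normalization, filtering, sample weights, thresholds, the samples in the fit, the trend, the set test, the window and each sample left out in turn.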

Results

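Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in age-associated B cells sorted from the spleen. These are B cells that accumulate with age and in lupus and are typically marked by CD11c (Itgax) and T-bet (Tbx21). The mice were 20-week-old MRL/lpr animals, a strain with a Fas mutation that develops a disease like systemic lupus erythematosus, reconstituted with a mixture of bone marrow of 3 genotypes. Tlr9, the endosomal receptor for CpG DNA, was absent (KO), present with the P915H change, which impairs its signalling (P915H), or intact (WT). Whether P915H removes all signalling of the receptor was not measured here. There were 3 samples per genotype and 9 in all. The table held 61540 peaks with a median length of 215 bp on build mm10, with values as log2 CPM of reads in peaks. The antilogs summed to 0.987 to 1.014 times the nominal CPM total per sample, so the sequencing depth of each sample is unknown. Cells of the 3 genotypes develop side by side in such mice, but the labels do not say which samples shared a host or whether the 3 samples of a genotype came from separate mice, so the p-values measure the spread between these samples, which may in part be technical.

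The first principal component took 57.9% of the variance and ordered the genotypes with WT in the middle. Its mean score was -76.5 ± 29.2 (SD, n = 3) in KO, 13.1 ± 17.6 in WT and 63.4 ± 11.6 in P915H. KO replicate 1 lay nearest to WT among the KO samples, at -44.9, and WT replicate 3 stood apart on the second component, at 70.5. Pearson correlations across peaks were 0.965 to 0.974 within KO, 0.963 to 0.977 within WT and 0.972 to 0.979 within P915H. Between genotypes they were 0.854 to 0.931 for KO and P915H, 0.899 to 0.968 for KO and WT and 0.93 to 0.97 for P915H and WT. Both ranges against WT overlap the range within WT (peaks are not independent replicates).

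**Figure D1:**
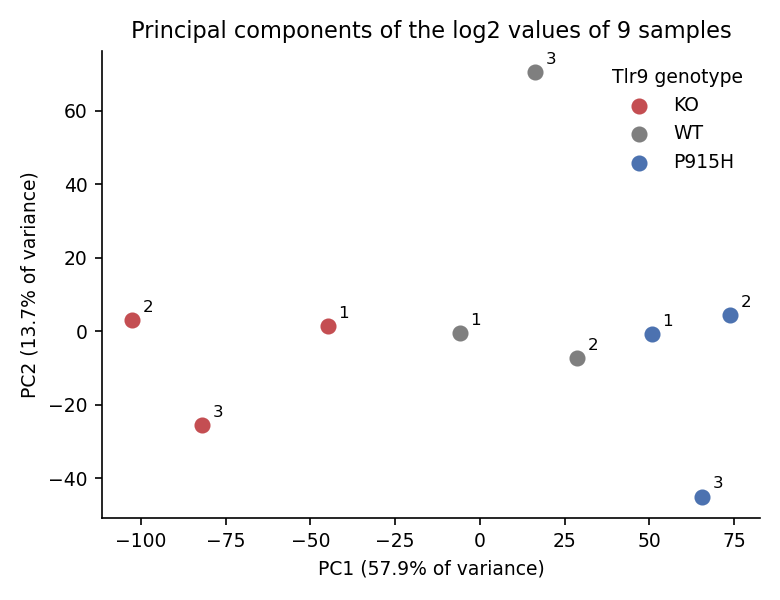
Scores of the 9 samples on the first 2 principal components of the log2 values, colored by Tlr9 genotype and numbered by replicate, with each axis giving its percent of the variance. The KO samples lie between -102.6 and -44.9 on the first component, the WT samples between -5.9 and 28.8 and the P915H samples between 50.8 and 73.8.

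The Tlr9 gene itself carried 2 peaks, both at the same end of the gene on chromosome 9. The peak at 106222230 to 106222641 had a log2 value of 5.87 ± 0.13 (SD, n = 3) in KO, 6.03 ± 0.07 in P915H and 6.09 ± 0.10 in WT. The peak at 106222910 to 106223290 had 3.51 ± 0.06, 3.35 ± 0.08 and 3.57 ± 0.07. Neither passed the threshold in any comparison, with limma adjusted p of 0.294 and 0.845 for KO against WT. The labels do not give the deleted part of the gene, and a peak outside it checks nothing, so these values neither bear out nor contradict the genotype labels.

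The comparison of KO with WT asks what the absence of the receptor changes. Among 61540 peaks, 12 passed limma's test at an adjusted p under 0.05, of which 3 were more accessible in KO and 9 less. The peaks that gained accessibility were at the heavy chain locus 3890 bp from Ighe, the epsilon constant gene, by 4.33-fold, within Itga5, the fibronectin-binding integrin alpha 5, by 2.10-fold, and within Sox5, a transcription factor gene of the age-associated B cell list, by 2.08-fold. The peak near Ighe (chromosome 12, 113265088 to 113265373) went from 2.22 ± 0.24 (SD, n = 3) in WT to 4.33 ± 0.33 in KO. It lies between the bodies of Igha and Ighe, and its assignment to Ighe by distance does not show which of them it regulates. The peak in Sox5 (chromosome 6, 144659476 to 144659685) went from 3.70 ± 0.08 to 4.76 ± 0.06. The smallest adjusted p, 0.00134, belonged to a peak within Mst1, which encodes macrophage-stimulating protein (chromosome 9, 108083259 to 108083472), which fell by 2.99 on the log2 scale (SE 0.19) from 3.70 ± 0.14 in WT to 0.71 ± 0.27 in KO.

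The other 8 lower peaks lay in or near Niban1, Rpap3, Igf2bp2, Dynlt1b, Zcwpw2, Tmco3, Sytl3 and Dse. The peak 19868 bp from Niban1 was near the floor of the table in all KO samples, with a mean of -8.11 ± 0.33 against 1.78 ± 0.28 in WT. Its log2 fold change of -9.89 therefore depends on the value the authors gave to a peak with few or no reads. The fall was 2.05 on the log2 scale 52594 bp from Rpap3 and 1.97 within Igf2bp2, an RNA-binding protein gene. The remaining 5 had log2 fold changes from -1.47 near Dynlt1b to -1.18 within Dse. Of the 12 peaks, 11 shared the same limma adjusted p, 0.0483.

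Of the 19 gene lists fixed before the data were examined, 1 differed from the other peaks in KO against WT by limma's camera test. Peaks of the follicular and naive B cell list, genes of resting mature B cells such as Foxp1, Bach2 and Ccr6, were less accessible in KO (adjusted p = 2.57e-05, median log2 fold change -0.18 over 322 peaks of 17 genes). The estimated correlation among the peaks of this list was 0.175, against the preset of 0.01, and with it the adjusted p was 0.773. The fry test gave 0.300. None of the 322 peaks passed over all peaks, and adjusted over the list alone 19 were lower and 1 higher. Without the 76 peaks of Foxp1 the list kept its direction, with an adjusted p of 0.00675. The lowest p values of the list were at Bach2, a repressor of plasma cell differentiation (log2 fold change -1.46, limma adjusted p = 0.0583), and near the chemokine receptor gene Ccr6 (-1.06, 0.0592).

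The age-associated B cell list had 1 higher peak, in Sox5, over all peaks and adjusted over the list alone. Genes of the other lists gave values short of the threshold. A peak 9034 bp from Il10, the gene of an immunoregulatory cytokine, had a log2 fold change of 1.02 (limma adjusted p = 0.0583), and a peak 15450 bp from Batf3 had 0.96 (0.0592). For the cytokine and cytokine receptor list, 8 peaks were higher and 11 lower when adjusted over the list alone. For the plasmablast and plasma cell list these counts were 6 and 2. For the germinal centre list they were 0 and 4, for the macrophage and monocyte list 0 and 5, for the dendritic cell list 4 and 1, for the T cell list 4 and 4, for the natural killer cell list 3 and 2, for the AP-1 list 1 and 2, and for the neutrophil list 1 and 0. At an unadjusted p under 0.05, 11531 peaks (18.7%) passed by limma, and at an adjusted p under 0.1 the counts were 785 higher and 2040 lower. The count of 12 was not stable. It was 3340 without KO replicate 1, 2 without KO replicate 2 or 3, and 1 without any single P915H or WT sample. A P915H sample enters this comparison only through the shared spread and the replicate term. Most of the 12 peaks shared an adjusted p just under the threshold, so they could lose it together. Without the replicate term the count was 6846 (2525 higher, 4321 lower), and it was 705 after quantile normalization, 643 with each sample centred on its median, 1536 with sample weights and 1 with only the 6 KO and WT samples.

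The comparison of P915H with WT asks what the P915H change in the receptor alters while the receptor remains. Of 157 peaks past limma's threshold, 155 were less accessible in P915H and 2 more. The lower peaks included sites at immune genes of the fixed lists. Within Ctla4, an inhibitory receptor gene of the T cell list (chromosome 1, 60913391 to 60913603), the value fell by 1.23 on the log2 scale, from 4.17 ± 0.28 (SD, n = 3) in WT to 2.94 ± 0.20 in P915H (limma adjusted p = 0.0258). A peak 16224 bp from Il10 (chromosome 1, 131003199 to 131003621) fell by 0.96, from 3.31 ± 0.18 to 2.35 ± 0.12 (0.0473). A peak within Tent5c, a poly(A) polymerase gene of the plasmablast and plasma cell list, fell by 0.88 (0.0342). A peak within Tnfsf13b, which encodes the B cell survival factor BAFF, fell by 0.87 (0.0295).

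The largest falls were at peaks that were weak in P915H. The log2 fold change was -3.40 within Lmo7, -2.82 within Dtd1, -2.73 near Tnfrsf11a (the receptor RANK), -2.70 within Osbpl3, and -2.69 at a peak 25102 bp from Ptprc (CD45). That last peak (chromosome 1, 138037542 to 138037757) was at -0.33 ± 0.23 (SD, n = 3) in P915H, 2.36 ± 0.24 in WT and 3.31 ± 0.21 in KO. Peaks assigned to Anxa5, Scfd2, Gm13304 and Pik3c2g had log2 fold changes from -2.66 to -2.42, and a peak on chromosome X at 125339643, over 100 kb from any gene, had -2.92. The 2 higher peaks were within Zfyve28 (1.15, limma adjusted p = 0.0150) and on chromosome 8 at 120977083, over 100 kb from any gene (1.75, 0.0352).

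No gene list differed from the other peaks in P915H against WT by camera, where the smallest adjusted p was 0.177. By fry, which does not compare a list with other peaks, no list moved on balance in one direction (smallest adjusted p 0.0758), while its test for change in either direction passed for 9 of the 19 lists here and for all 19 in KO against WT and in KO against P915H. The plasmablast and plasma cell list had 1 lower peak, at Tent5c, the cytokine list 2, near Il10 and within Tnfsf13b, and the T cell list 2, both at Ctla4. Adjusted over the list alone, 1 peak of the plasmablast list, 5 of the cytokine list, 5 of the T cell list, 2 of the germinal centre list (both at Fas, the gene mutated in this strain), 1 of the interferon list and 1 of the neutrophil list were lower, and none was higher. Of the 155 lower peaks, 21 lay on Y and 8 on X, and 58 lay in 8 clusters of at least 3 called peaks. These clusters included the major urinary protein genes on chromosome 4 (8 called peaks from 60104304 to 60786293 and 8 from 61303164 to 62177519), a defensin region on chromosome 8 with 10, the distal end of Y with 18, and Mid1 on X with 5. At an unadjusted p under 0.05, 4749 peaks (7.7%) passed by limma.

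The count of 157 fell to 7 without WT replicate 1, 16 without P915H replicate 1, 22 without P915H replicate 2, 29 without WT replicate 2, 57 without KO replicate 3, 90 without KO replicate 2, 103 without P915H replicate 3, 105 without KO replicate 1 and 0 with only the 6 P915H and WT samples. It was 1060 (115 higher, 945 lower) without the replicate term and 627 with sample weights.

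The comparison of KO with P915H asks whether a missing receptor and a present receptor with impaired signalling leave the chromatin in the same state. They differed at 9548 peaks (15.5%), 4028 more and 5520 less accessible in KO, assigned to 4593 genes. Peaks less accessible in KO included a peak within Foxp1 (chromosome 6, 99350661 to 99350872) by 2.93-fold, and a peak within Bach2 (chromosome 4, 32304293 to 32304508) by 3.31-fold. Peaks within Sox5, Ctla4 and Tent5c were more accessible in KO, by 3.19-fold, 3.49-fold and 2.98-fold, as were a peak 16224 bp from Il10, by 3.45-fold, and a peak 42911 bp from Irf1, by 3.29-fold (limma adjusted p from 0.000326 to 0.000699).

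**Figure D2:**
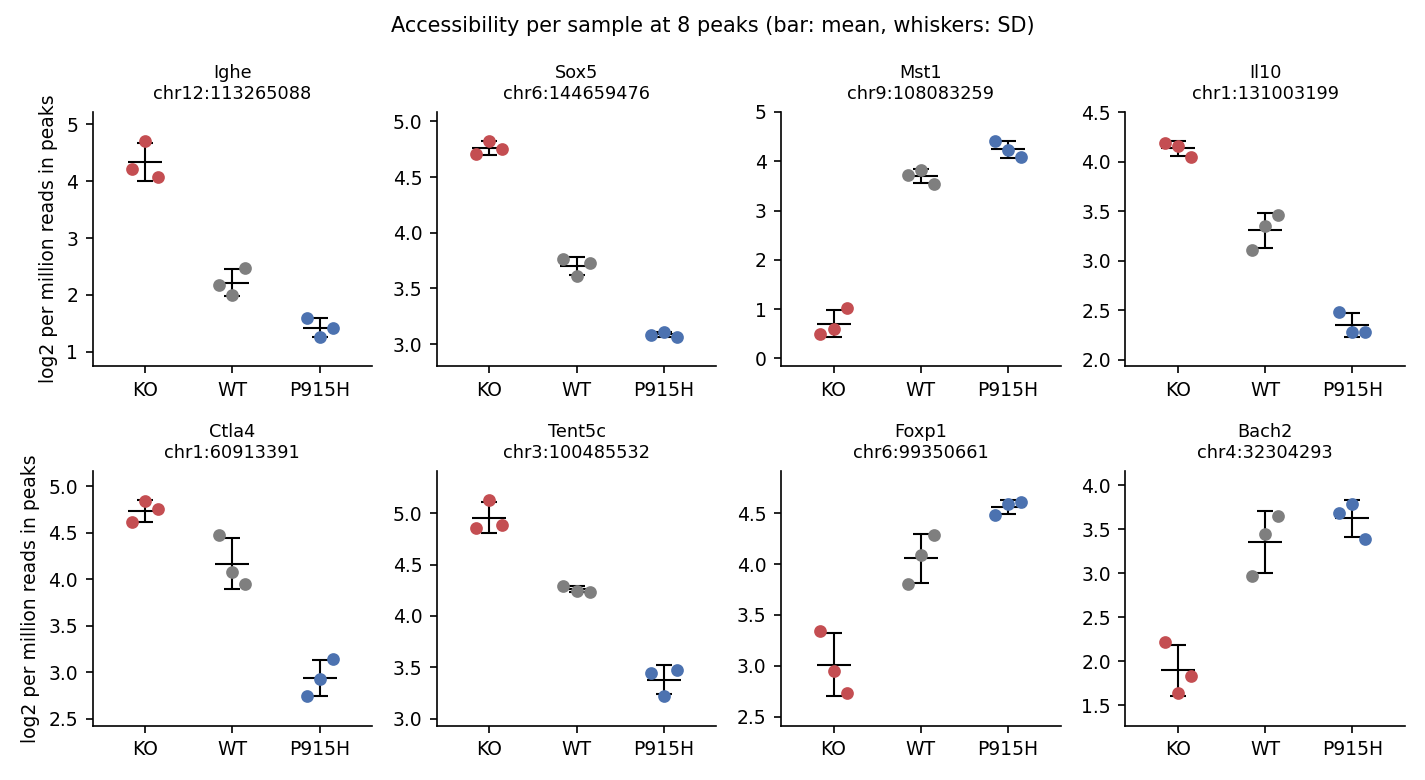
Log2 accessibility (CPM in peaks) at 8 peaks, each point a sample and each genotype with its mean and SD (n = 3), after the authors' removal of a per-peak replicate effect, with axes that do not start at 0. WT lies between KO and P915H at all 8, for example at the Sox5 peak with 4.76 in KO, 3.70 in WT and 3.09 in P915H.

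The follicular and naive B cell list was lower in KO than in P915H by camera (adjusted p = 4.78e-05, median log2 fold change -0.22), but not with an estimated correlation (adjusted p = 0.767) or by fry (0.121). Of its 322 peaks, 71 fell, 8 rose and 243 did not pass. Adjusted over the list alone, 89 fell and 13 rose. Of its 17 genes, 9 had lower peaks alone, 5 had both and 3 had none. Foxp1 gave 30 of the 71 lower peaks, and without it the adjusted p was 0.0180. Bach2 had 9 lower and 3 higher peaks, and Satb1, a chromatin organizer gene, had 6 lower of 8. With a sample left out, the lower peaks numbered 8 to 39 at Foxp1, 1 to 14 at Bach2 and 2 to 6 at Satb1. A peak in Foxo1, a transcription factor gene of resting lymphocytes, fell by 2.09 on the log2 scale (SE 0.37), and a peak near Ccr6 by 1.34 (SE 0.18). The list passed camera at the preset correlation without each of the 9 samples in turn, with adjusted p from 4.49e-07 to 0.00147.

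The dendritic cell list, fixed as a marker list of another cell type, was higher in KO by camera (adjusted p = 0.0338, 0.409 with an estimated correlation) and by fry (0.00978). Its 105 peaks held 24 higher and 8 lower ones, and 30 and 11 when adjusted over the list alone. Of the 24, 12 (5 to 13 with a sample left out) were at Tcf4, a transcription factor gene that B cells also use, and without Tcf4 the adjusted p was 0.409. A Tcf4 peak (chromosome 18, 69601139 to 69601301) had a log2 fold change of 2.26, and a peak near Batf3 had 1.61. Zbtb46 and Flt3 had lower peaks, at -2.15 and -2.13, although another Zbtb46 peak had 1.63. Its adjusted p was 0.0762 without P915H replicate 3, 0.0685 without KO replicate 1 and 0.0560 without WT replicate 3, and it passed in the other 6 fits that left out a sample.

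The plasmablast and plasma cell list had 18 higher and 6 lower peaks of 133, and 24 and 10 adjusted over the list alone. Camera gave an adjusted p of 0.0566 and fry 0.0243. Tent5c rose by 1.58 on the log2 scale, and Mzb1, a chaperone gene for antibody assembly, by 0.87 (SE 0.13). The T cell list had 15 higher and 8 lower of 68 (18 and 11 over the list alone), with 0.190 by camera and 0.00978 by fry. Its members Ctla4 and Cd3g had peaks with log2 fold changes of 1.80 and 2.05.

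The other lists had called peaks in both directions, except for the neutrophil list with 2 higher ones, and none of them passed camera. The age-associated B cell list had 17 higher and 16 lower peaks of 168 (21 and 16 over the list alone), with Sox5 at 1.67, Apoe at 1.26 and Fcer1g at 2.02. The germinal centre list had 8 higher and 26 lower of 171 (10 and 32), with Fas at 1.63 and Bach2 at -1.72. The B cell receptor signalling list had 13 and 15 of 232 (11 and 12), with Dok3 at 0.87 and the kinase gene Blk at -0.94. The endosomal Toll-like receptor list had 5 and 8 of 117 (5 and 7), with Lgmn, a protease gene, at 0.98 and a peak near the adaptor gene Myd88 at -1.54. The NF-kB list had 9 and 15 of 214 (6 and 13), with Nfkb1 at 1.13 and Bcl2a1b at -0.94.

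The type I interferon list had 7 higher and 3 lower of 79 (7 and 3 over the list alone), with the peak assigned to Irf1 at 1.72. The cytokine list had 21 and 18 of 158 (26 and 24), with peaks near Il10 at 1.92 and 1.79 and Tnfsf13b at 1.42. The antigen presentation and costimulation list had 15 and 8 of 154 (13 and 8), with a peak of Pdcd1lg2, the gene of PD-L2, at 2.10 and Cd80 at 0.94. Most called peaks of Pdcd1lg2 went the other way, with 2 higher and 5 lower of 17 and a median of -0.195. The AP-1 list had 12 and 19 of 209 (12 and 19), with peaks 53319 bp from Myc at 1.46 and 37470 bp from Fos at -1.95. The cell cycle list had 2 and 5 of 109 (1 and 1), and the apoptosis list 9 and 14 of 190 (8 and 13). Of the remaining lists of other cell types, natural killer cell genes had 4 and 7 of 38 (5 and 8), macrophage and monocyte genes 6 and 8 of 59 (6 and 11), neutrophil genes 2 and 0 of 12 (2 and 0), and erythroid genes 2 and 1 of 14 (2 and 1). Their members Cebpe, Cebpb and Txk had peaks at 2.04, -1.38 and -1.78. The mean and the median log2 fold change of a list had opposite signs for the cytokine list alone (0.01 and -0.03).

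**Figure D3:**
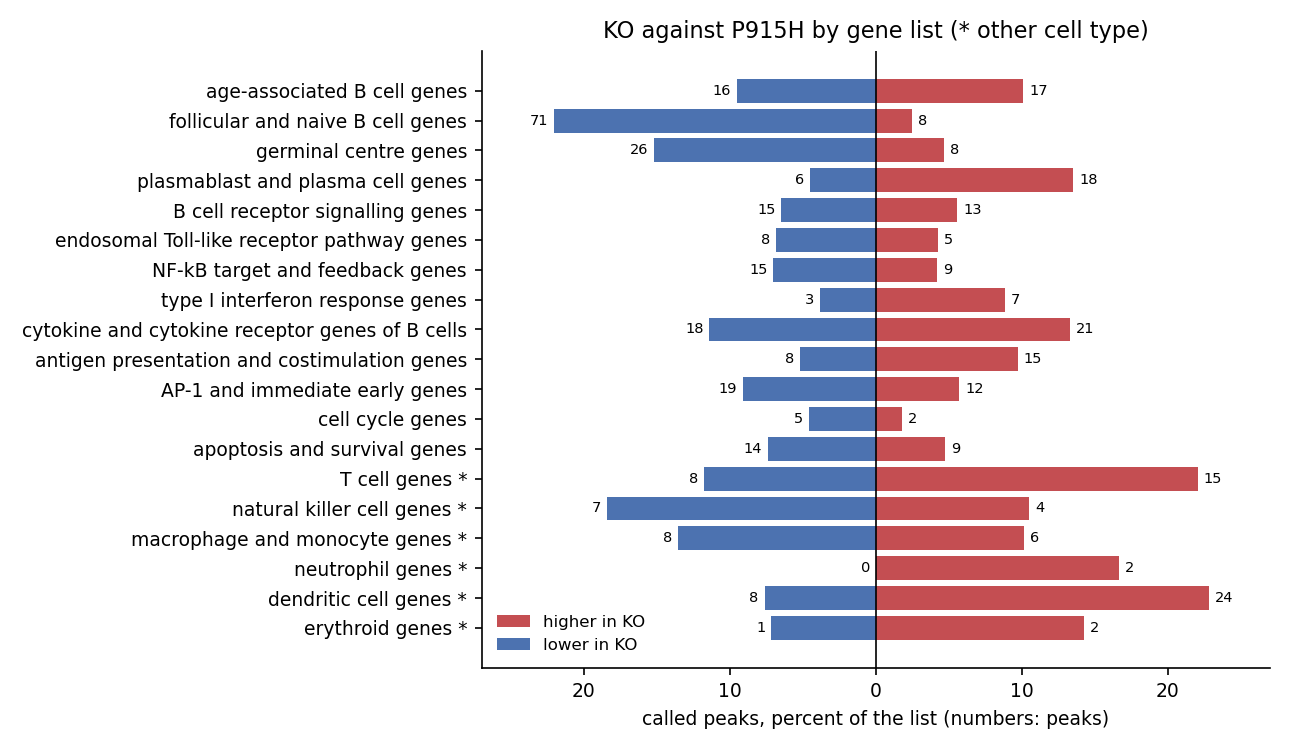
Called peaks of each of the 19 gene lists in KO against P915H, as percent of the peaks of the list, to the right where higher and to the left where lower in KO, with the number of peaks at each bar; lists with an asterisk are markers of other cell types. The follicular and naive B cell list shows 71 lower and 8 higher peaks and the dendritic cell list 24 higher and 8 lower.

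Some of the largest single differences were at peaks with values far below 0 on the log2 scale in one genotype. A peak 18849 bp from Sik1 had a log2 fold change of 7.06 (SE 1.32) with P915H at -5.14 ± 1.82 (SD, n = 3), and peaks assigned to Nr5a2 and 9530057J20Rik had 6.70 and 6.56. A peak within Scfd2 had 4.04 (SE 0.32), from 0.16 ± 0.58 in P915H to 4.20 ± 0.13 in KO, and a peak near Ccdc114 had 3.83. In the other direction the Niban1 peak had -10.4, a peak within Lhfp -4.28 and the Mst1 peak -3.54 (SE 0.19). That Niban1 peak does not stand for its gene, where 7 of 13 peaks were higher and 2 lower, with a median of 1.05. Peaks assigned to Megf10, Mgme1, Saa4, Klf6 and Agap1 had values from -3.14 to -2.84. Across the table, 16 peaks had a genotype mean under -2, with the lowest mean in KO at 9, in P915H at 7 and in WT at 0. Fold changes at such peaks depend on the value given to a peak with few reads.

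Called peaks lay near gene ends less often than other peaks did. Peaks were not matched for mean value, so place and peak strength were not told apart. Of the peaks higher in KO, 13.1% lay within 1 kb of either end of a gene, against 30.5% of the other peaks, and of the peaks lower in KO 7.9%, against 31.4%. For the peaks lower in P915H than in WT the share was 9.7%, against 29.4% (Fisher's exact test across peaks, two-sided, p = 4.66e-09, with neighboring peaks not independent).

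The heavy chain constant region held a run of peaks that were more accessible in KO than in P915H, chosen for description after its values were seen. Of the 19 peaks assigned to Igha or Ighe, 11 were called higher and none lower, with a median log2 fold change of 0.91. The peak near Ighe named above rose by 2.91 on the log2 scale (SE 0.22, limma adjusted p = 0.000326), and a peak at one end of Igha (113260285 to 113260593) by 3.76 (SE 0.57). Outside Igha, on the side away from Ighe, peaks starting at 113232359, 113244830 and 113253914 had 1.59, 1.26 and 1.44. The 23 other peaks of the constant genes had a median of 0.15, with 3 higher and 1 lower. With a sample left out, these 23 had a median of -0.009 to 0.32, with 0 to 4 higher and 0 to 1 lower. The 3 higher ones were at Ighg2c (1.04 and 0.69) and Ighg2b (1.08), so the rise was not confined to Igha and Ighe. At these 3 the log2 fold change of KO against WT was 0.48, -0.04 and 0.11. That of P915H against WT was -0.56, -0.73 and -0.97, and none of these values against WT passed the threshold. The count at Igha and Ighe was 8 to 11 when each sample was left out in turn, and the median was 0.86 to 0.94 under the other scalings. Whether the donor lines carry different heavy chain alleles was not tested, so an allotype difference cannot be told apart from an effect of genotype here.

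**Figure D4:**
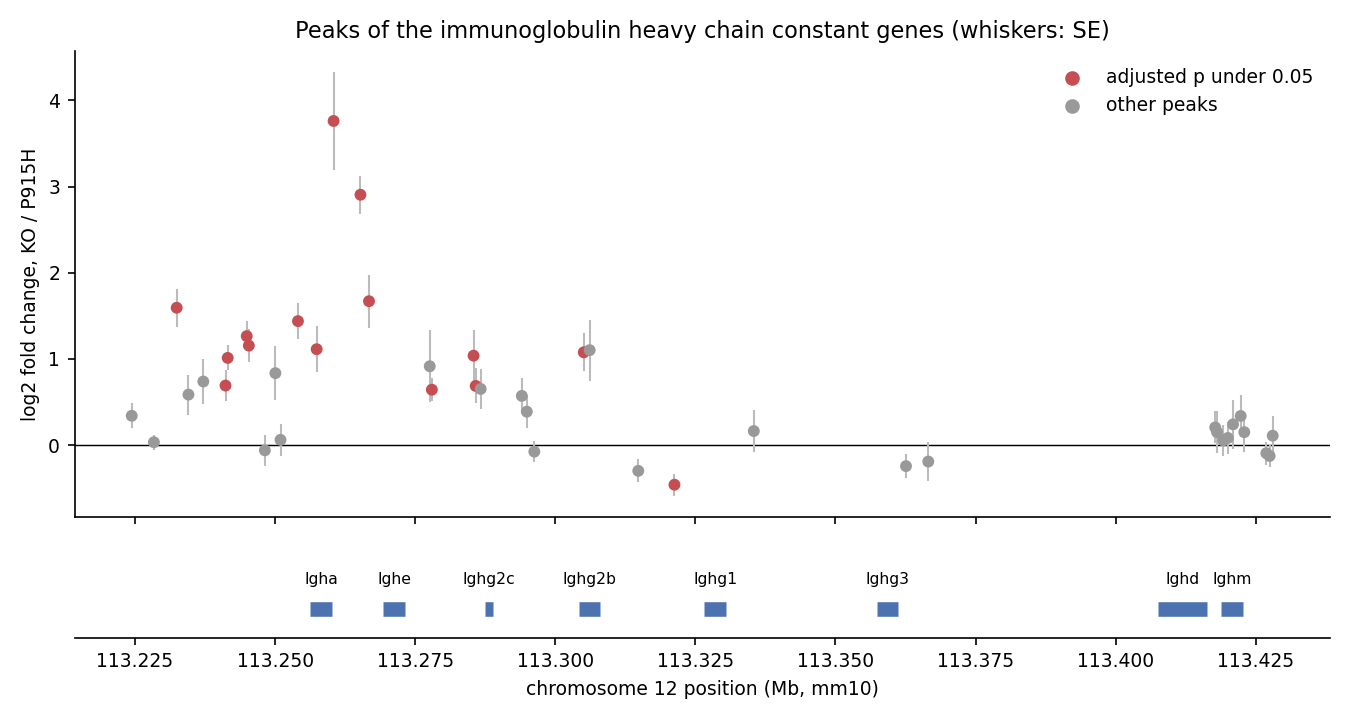
Log2 fold change of KO against P915H at each peak assigned to a heavy chain constant gene, with its SE, along chromosome 12 in Mb on mm10, and below it the bodies of the constant genes. Peaks around Igha and Ighe reach 3.76 and 2.91, and those assigned to Ighm lie between -0.13 and 0.34.

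The count of 9548 was 17069 (7443 higher, 9626 lower) without the replicate term and 5703 without the 25% of peaks with the lowest mean. It fell to 3225 without P915H replicate 2 (1812 higher, 1413 lower), 3570 without KO replicate 3 (1824 and 1746) and 3817 without KO replicate 2 (1772 and 2045). It was 4731 without P915H replicate 3 (2441 and 2290) and 5941 without P915H replicate 1 (2361 and 3580). Lower peaks thus outnumbered higher ones in the full fit, but not without P915H replicate 2, P915H replicate 3 or KO replicate 3.

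The effects of the alleles against WT were set side by side because both comparisons use the same WT samples. Across peaks, the covariance of the log2 fold changes of KO and of P915H against WT was -0.0337, whereas unchanged groups simulated against shared WT samples gave 0.0231, a difference of -0.0568. Pearson's r across peaks was -0.274, against 0.5 in the simulation, and 47.5% of peaks had the same sign in both, against 66.7%. At an adjusted p under 0.1 the lists shared 2 lower peaks of 2040 and 322, where independent lists would share 10.7, although lists against the same WT samples are not independent. The WT samples were not split between the comparisons, and r was 0.02 without WT replicate 1, with a difference of covariances of -0.0381.

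Around Tlr9, the share of called peaks was compared with the rest of the genome, since an allele bred into another strain carries flanking DNA. Within 10 Mb of Tlr9, 1 of 616 peaks was called in KO against WT, the Mst1 peak, against 11 elsewhere (Fisher's exact test, two-sided, p = 0.114, adjusted 0.205 over 9 window tests). Within 20 Mb there were 2 (Fisher's exact p = 0.0189). In KO against P915H, 74 of the 616 peaks around Tlr9 were called, a lower share than the 15.6% elsewhere (exact p = 0.0160, adjusted 0.0720). The share was 17.3% around Ptprc, against 15.5% elsewhere (exact p = 0.241, adjusted 0.310). Within 20 Mb of Ptprc the share was 19.9% against 15.4% (exact p = 0.000199, not among the adjusted tests). Around the heavy chain constant genes 21.2% were called against 15.5% (exact p = 0.00042, adjusted 0.00378). Neighboring peaks are not independent, so these p-values are too small.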

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

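Loess normalization, a fit without the intensity trend, a robust spread and the limit of 2 kb from a gene body were chosen after the data had been seen. The replicate block was planned as an alternative and became part of the reported fit, as described above. KO against WT gave 12 peaks with the block and 6846 without it, 1 without the 25% of peaks with the lowest mean, 705 with quantile normalization, 643 with each sample centred on its median, 1 with only the 6 samples compared, 1536 with sample weights, 2825 at an adjusted p under 0.1, 4 without the intensity trend, 408 with a robust spread, and 1 to 3340 with a sample left out. P915H against WT gave 157 with the block and 1060 without it, 0 with only the 6 samples (4749 peaks had an unadjusted p under 0.05 in the reported limma fit), 627 with sample weights, 326 at an adjusted p under 0.1, 86 without the trend, and 7 to 111 with a sample left out. KO against P915H gave 9548 with the block and 17069 without it, 4679 with a minimum fold of 2, 5703 without the lowest 25%, and 3225 to 10991 with a sample left out; the other alternatives gave 8588 to 13560. The lists called in KO against WT, 1 in the reported fit, were 2 without the block, with quantile normalization, with the 6 samples, with sample weights and within 2 kb of a gene body, 0 with an estimated correlation or fry, and 1 to 3 with a sample left out. In P915H against WT they were 0, and 0 to 1 with a sample left out. In KO against P915H they were 2, and 1 without the lowest 25% or with loess normalization, 0 with an estimated correlation, 3 with quantile normalization or within 2 kb of a gene body, 3 with fry (all higher, without the follicular and naive list), and 1 to 4 with a sample left out. The difference of covariances, -0.0568, was -0.0437 with quantile normalization and -0.0687 to -0.0381 with a sample left out. Near Tlr9, 1 peak became 2 in a 20 Mb window, with p under the threshold, 1 to 24 with a sample left out, 59 without the block and 5 with quantile normalization, the last pair with p above the threshold. For the 60 named results, 809 of 1094 alternative values stayed on the same side of the threshold, 285 lost it and 0 reversed. The losses were uneven. With only the 6 samples compared, 30 of 32 stayed in KO against P915H, 1 of 12 in KO against WT and 0 of 16 in P915H against WT. With each sample centred on its median all 32, 12 and 16 stayed. The smaller counts with fewer samples follow in part from fewer degrees of freedom, and otherwise the cause was not tested. A sample left out leaves 2 in its genotype. Motif sets, a GC correction, pseudocounts and count-based tests were not run.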

Other observations

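The tests of classes of mean value, of clusters, of single-copy Y genes and of the flanks of Ptprc were chosen after the results were seen, as were the genes and regions described first.

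Some genes held many peaks that differed between KO and P915H in the same direction. Of 198 genes with at least 6 called peaks, 58 had lower peaks alone, 40 higher peaks alone and 100 both. Foxp1, a transcription factor gene of mature B cells, had 30 lower and 0 higher of 76 peaks, with a median log2 fold change of -0.50. Pde4d, a cyclic AMP phosphodiesterase gene, had 21 lower of 25 (median -1.45), Zfp608 16 of 24 (-0.82) and Smad3, of TGF-beta signalling, 13 of 23 (-0.68). In the other direction, Zbtb20, which acts in plasma cells, had 20 higher and 3 lower of 36 (0.78), Cadm1 11 higher of 16 (1.27), and Cdk14 and Nr3c2 8 higher of 8 each (1.88 and 1.45). The medians kept their sign under quantile, median and loess scaling. With a sample left out the medians also kept their sign, for example -0.653 to -0.391 at Foxp1 and 1.681 to 2.039 at Cdk14. The counts moved more, and fell without any of several KO or P915H samples. The count at Pde4d was 14 to 22. The count at Foxp1 was 8 without KO replicate 2 or 3, 9 without P915H replicate 2 and 10 without P915H replicate 3. The count at Zfp608 was 8 without KO replicate 2 or 3, 4 without P915H replicate 2 and 6 without P915H replicate 3. Smad3 had 6 without KO replicate 3 or P915H replicate 2 and 8 without P915H replicate 3. Zbtb20 had 12 higher without KO replicate 3 and 13 without KO replicate 2, Cadm1 7 without KO replicate 3, Cdk14 5 without KO replicate 2 and Nr3c2 5 without KO replicate 3.

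The first principal component placed WT between KO and P915H, and the 9548 called peaks between these were the largest of the 3 counts. Loess normalization, which gave 9782 calls, moved fold changes by a median of only 0.015 and so decides little, but among 10 classes of peaks by mean value the median log2 fold change farthest from 0 was -0.027, against a median size of 0.99 for called peaks, which argues against an intensity-dependent difference between libraries as the cause. For cells of another type, which the sort for age-associated B cells is meant to remove, a limit was chosen in advance. It was 50% of a marker list's peaks at an unadjusted p under 0.05 in one direction. The highest share was 34.3%, for dendritic cell genes. Other cells in a sample need not reach that limit, so the share does not decide the question. The dendritic cell list had a median of 0.16, or 0.05 without Tcf4. The former lies above the range of 95% of 10000 random peak sets, which ended at 0.086. The T cell list had 0.18 (above 99.9% of random sets), and macrophage and monocyte genes -0.13 (above 0.9%). Natural killer (-0.11), neutrophil (0.17) and erythroid (-0.04) genes lay within the range of 95% of random sets. Cells of another type therefore stay open. The genotype of Tlr9, and a difference between the donor lines that carry its alleles, remain open and were not tested.

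Of the 10 splits of the 6 samples into equal groups, too few for a share under 0.05, the real split gave 9548 and the highest other 0 for KO against P915H, 12 and 69 for KO against WT, where 2 splits gave at least as many, and 157 and 670 for P915H against WT, where 2 did. The splits with 69 and 670 part the samples of only 1 replicate number, unlike the real split, which parts all 3. The other splits that part 3 gave 0 in each comparison. They mix the genotypes, however, and a difference between genotypes then adds to the spread, so these counts of 0 decide little.

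Of the 157 peaks called in P915H against WT, 58 (36.9%), all lower in P915H, lay in 8 clusters, many in repeated gene families such as Mup genes, which is short of the 50% set for copy number or strain sequence as the main cause and above the 25% set against it, so that explanation cannot be told apart from a change in chromatin for these clusters. The same spans had medians from 0.15 to 0.69 in KO against WT. For Y, the median log2 fold change in P915H against WT was -0.316 over 106 peaks below 90 Mb and -0.70 over 43 beyond. Peaks at single-copy Y genes had a median of 0.106 over 9 peaks, the lowest at -0.52, which argues against fewer Y chromosomes among the P915H cells. Mapping of repeated sequence, copy number between donor lines and an effect of the genotype stay open.

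Flanking DNA of another strain would raise the share of peaks with large changes around the modified gene. In KO against P915H, 6.33% of peaks within 10 Mb of Tlr9 were called with a fold of at least 2, below the share in most windows of the genome (27.2% of windows were lower). Within 5 Mb the share was 6.31%, against 7.61% elsewhere. Large changes were thus not concentrated in these windows, although a shorter stretch could be diluted in them. The 10 Mb window holds 616 of 61540 peaks, so its share says nothing on the source of the changes as a whole. The Mst1 peak stays open, as the only one within 10 Mb of Tlr9 called in KO against WT. There the exact p was 0.114, 0.0189 within 20 Mb, and 0.0100 to 0.107 with a sample left out, with 1 or 2 calls in all in 8 of those 9 fits. It was 0.246 without the replicate term (59 peaks of 6846) and 0.568 with quantile normalization (5 of 705). Around Ptprc the share was 9.29%, with 76.5% of windows lower (9.99% against 7.56% within 20 Mb, exact p = 0.00542), and around the heavy chain constant genes 12.18%, with 94.1% lower. The heavy chain share stood against 7.56% elsewhere (Fisher's exact p = 0.000164, adjusted 0.00148). The shares within 10 Mb of these loci are short of the highest 5% of windows. An allotype marker used in sorting therefore stays open at Ptprc and at the heavy chain locus, as does an effect of genotype, which was not tested apart from it.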
